A study of Homo sapiens with 480 samples.

How the data were processed

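Transcriptomes of 480 single cells were measured in 5 groups of 96: BJ fibroblasts, cells at day 2 and day 8 after induced viral expression of OCT4, SOX2, KLF4 and MYC, and cells of day 16 sorted into TRA-1-60 positive and negative fractions. The groups are called BJ, D2, D8, D16_pos and D16_neg in the figures. Per the labels' protocols, trypsinized cells were captured on Fluidigm C1 chips for mRNA sequencing and run with STRT protocols, and libraries of polyadenylated RNA were made with Nextera XT. Each group took its name from the label of its cells, and every cell was assigned by its label. No label names a separate culture, infection or chip, so each group counts as 1 sample and its cells are not replicates.

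The deposited values are FPKM, 1 table per group with 27021 genes; the submitters' processing notes name STAR, Cuffnorm and the genome build hg19, with no versions given in the sources used here. Whether the 5 tables were normalized together is not stated. FPKM are not counts. After the other results were seen, low values under 3 were searched for the steps that whole reads leave, as ratios between 2 cells of a group that pile up at 1 value. Such steps stood out in 2188 of 20439 pairs of cells (10.7%; 19.0% of pairs at day 8 and 22.2% in the negative fraction), while whole reads simulated for BJ over 27021 genes at 1000000 per cell gave them in 190 of 190 pairs and the same values made not whole in 0 of 190. Steps are thus present in some pairs and not in most, which leaves most cells without a common unit. No depth was therefore taken from the steps, relative or absolute; the depth per cell is unknown, and limits of detection per cell were not computed. Median FPKM totals per cell were 751450 in BJ, 798970 at day 2, 809960 at day 8, 647380 in the positive and 674080 in the negative fraction. Single cells reached far higher totals, up to 7.494e+07 in 1 day-2 cell. At day 2 small RNA genes, counted with the mitochondrial RNA genes, took up to 94.1% of a cell's total. FPKM were therefore rescaled to a total of 1000000 per cell, and a gene counted as detected at a rescaled value of 1 or more.

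Cells were kept with at least 2000 detected genes and with ACTB or GAPDH detected. This left 460 of 480 cells, with 4, 0, 4, 1 and 11 left out in BJ, day 2, day 8, the positive and the negative fraction; no pair of cells held identical values. Doublets cannot be called from FPKM of 96 cells per group; leaving out the 5% of cells with most detected genes was an alternative. No column of the tables was left unused.

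For each comparison the effect of a gene was log2((mean in A + 1)/(mean in B + 1)) over kept cells, which understates the ratio of low genes. No test, p-value or standard error was computed for any comparison of groups, as there is 1 culture per group. Shares of cells carry exact binomial (Clopper-Pearson) 95% intervals. For a share of 0, the limit that 3 counts allow was 3.26% in BJ and at day 8, 3.13% at day 2, 3.16% in the positive and 3.53% in the negative fraction. Comparisons were day 2 against BJ, day 8 against day 2, positive against negative fraction, and each fraction against day 8; day 8 and both fractions were also set against BJ for the tables of levels.

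There were 27 gene lists, fixed before the data were examined, as were the comparisons, the cell filter, the rule for named genes and the alternatives except where said. They covered reprogramming factors, pluripotency, fibroblast, fibroblast surface markers, contractile and actin cytoskeleton, epithelial, mesenchymal transcription factors and markers, AP-1 factors, TEAD and YAP, S phase, G2 and M phase, p53 targets and senescence, inflammatory and SASP (the senescence-associated secretory phenotype), interferon response, glycolysis, oxidative phosphorylation, cholesterol synthesis, DNA methylation and chromatin, neural, mesendoderm and endoderm, trophoblast, keratinocyte, endothelial, blood and immune, adipocyte, bone and cartilage, heat shock and cell stress, and housekeeping genes. A member was measured where its mean was 1 or more in either group. It was called at least 2-fold higher or lower where its log2 ratio was 1 or more in size and the difference of mean log2(value + 1) over cells had the same sign. List medians were set against 10000 random lists matched on the decile of mean expression. A cell had the pluripotency programme with at least 3 of 29 list genes detected, PODXL not counted because the sort used an epitope of its product, and the fibroblast programme with at least 17 of 34 genes.

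Named genes were the 10 highest and 10 lowest of each comparison by difference of mean log2(value + 1), among genes with a mean of at least 10 in the higher group, a log2 ratio of 1 or more in size and shares of cells that differed by at least 25 percentage points in the same direction. Mitochondrial and ribosomal protein genes, uncharacterised and small RNA symbols, and XIST and genes of the Y chromosome were not named by this rule. From each list up to 4 members with the largest differences were named, with the 4 factors and TEAD4, FOSL1, NANOG, GDF3, LIN28A, ANPEP, CD44, PROCR, CDH1, EPCAM, PODXL and THY1. RPL21 and a few genes given with table splits, with single values from the lists, were chosen after their values were seen. A RefSeq table of GRCh38.p14 served only for gene names and for which genes neighbour each other, since the files use hg19, and no coordinates are given.

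Alternatives were FPKM as deposited, scaling on the housekeeping list, mitochondrial RNA genes left out of the rescaling, a pseudocount of 0.1, the difference of mean log2 values, means trimmed by 10%, no cell left out, only cells with at least 4000 genes, the 5% of cells with most genes left out, all list members, and, for shares, detection above 0, at 10 or more or among the 3000 highest genes of the cell. Leaving small RNA genes out of the rescaling was added after seeing the data. It left out the mitochondrial RNA genes too, so these alternatives are not separate checks. A list median counted as moved where it changed by more than 1.5-fold, and a share where it left its interval.

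The calculations were tested on simulated data made for day 2 against BJ over 11661 genes. Of 50 genes planted at each fold, 100% at 0.25-fold, 98% at 0.5-fold, 100% at 2-fold and 100% at 4-fold had the right direction, with median absolute errors of 0.20, 0.23, 0.28 and 0.24 in log2. The fibroblast list planted at 4-fold was found at a median of 1.97. For this median, the errors and the 2-fold differences of unchanged genes, the median log2 ratio of unchanged genes was first subtracted. The comparisons of groups made no such subtraction, so these values do not give the error of uncorrected ratios. Of 96 simulated cells, 24 were given the pluripotency programme and 26 were found, against 1 found with none planted. It was planted with more genes and at a higher level than a cell needs to be counted, so finding these 24 cells could not fail. Of 5150 unchanged genes with a BJ mean of at least 10, 5.79% reached a 2-fold difference from the sampling of cells alone. The planted genes outside the fibroblast list had such means too, so the errors of list members with means between 1 and 10 were not measured. Values were drawn gene by gene from BJ cells, which leaves out variation that the genes of a cell share. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.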

Results

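Single-cell RNA sequencing was used to follow BJ fibroblasts, an established line of neonatal human skin fibroblasts, during reprogramming towards pluripotency by viral expression of the transcription factors OCT4 (POU5F1), SOX2, KLF4 and MYC. The 5 groups were BJ cells without factors, cells at day 2 and day 8 of factor expression, and cells of day 16 sorted by the surface epitope TRA-1-60 into a positive and a negative fraction. Each group held 96 cells, of which 92, 96, 92, 95 and 85 were kept, in that order. The median kept cell had 5678 genes at a value of 1 or more in BJ, 5880.5 at day 2, 5915 at day 8, 5869 in the positive fraction and 5871 in the negative fraction. Low-complexity cells were most frequent in the positive fraction, where 32 of 95 kept cells had fewer than 4000 genes, against 8 of 92 in BJ, 15 of 96 at day 2, 4 of 92 at day 8 and 3 of 85 in the negative fraction. The tables give no read counts, so the depth of each cell is unknown.

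**Figure D1:**
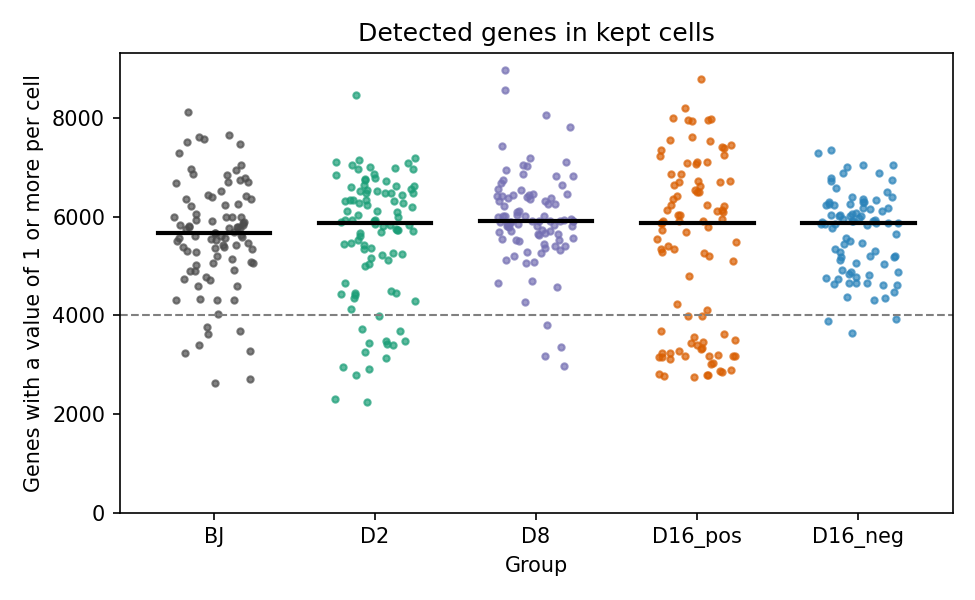
Number of genes with a rescaled value of 1 or more in each kept cell (points, 1 per cell) of the 5 groups, with the median of each group as a bar and 4000 genes as a dashed line. The medians lie between 5678 and 5915, and 32 of the 95 kept D16_pos cells lie under the line.

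Levels below are means over kept cells of FPKM rescaled to a total of 1000000 per cell, and shares are percentages of kept cells with a value of 1 or more. Each group is 1 culture as far as the labels say, so no difference between groups has a replicate check and none was tested. The 5 groups are 5 separate tables and nothing states whether they were normalized together, which holds for every level set across them. Exact binomial (Clopper-Pearson) 95% intervals of any share reached at most 10.5 to 11.2 percentage points to either side, depending on the group, and cover counting error only. Members of a gene list are called at least 2-fold higher or lower by their means. For some lists the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean level.

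The factors and the pluripotency genes set the frame for the comparisons. MYC averaged 44.5 in BJ cells, 988 at day 2, 375 at day 8, 75.1 in the positive fraction and 334 in the negative fraction; its lower level in the positive fraction, against the negative fraction and against day 8, turned to a higher one under housekeeping scaling. SOX2 averaged 0.155 in BJ cells, 61.9 at day 2, 56.5 at day 8, 154 in the positive and 34.2 in the negative fraction. KLF4 averaged 7.45, 27.99, 10.9, 15.3 and 20.8 in the same order. Viral and endogenous copies of a factor share 1 value in these tables. POU5F1 was listed at no more than 0.45 in any group. It lies in the major histocompatibility complex, where 1 of 150 protein-coding genes had a mean of 10 or more in any group, against 59 of 150 genes on either side of that stretch, so no level of POU5F1 was read from these tables. NANOG, a core pluripotency factor, averaged 172 in the positive fraction and at most 2.65 in the other groups, and LIN28A, an RNA-binding protein of pluripotent cells, averaged 138 in the positive fraction and at most 0.515 elsewhere. Surface genes of the fibroblast followed different courses: ANPEP (CD13) averaged 35.5 in BJ, 30.6 at day 2, 10.8 at day 8, 0.231 in the positive and 15.96 in the negative fraction, while THY1 (CD90) averaged 265, 101, 149.9, 351 and 222.

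**Figure D2:**
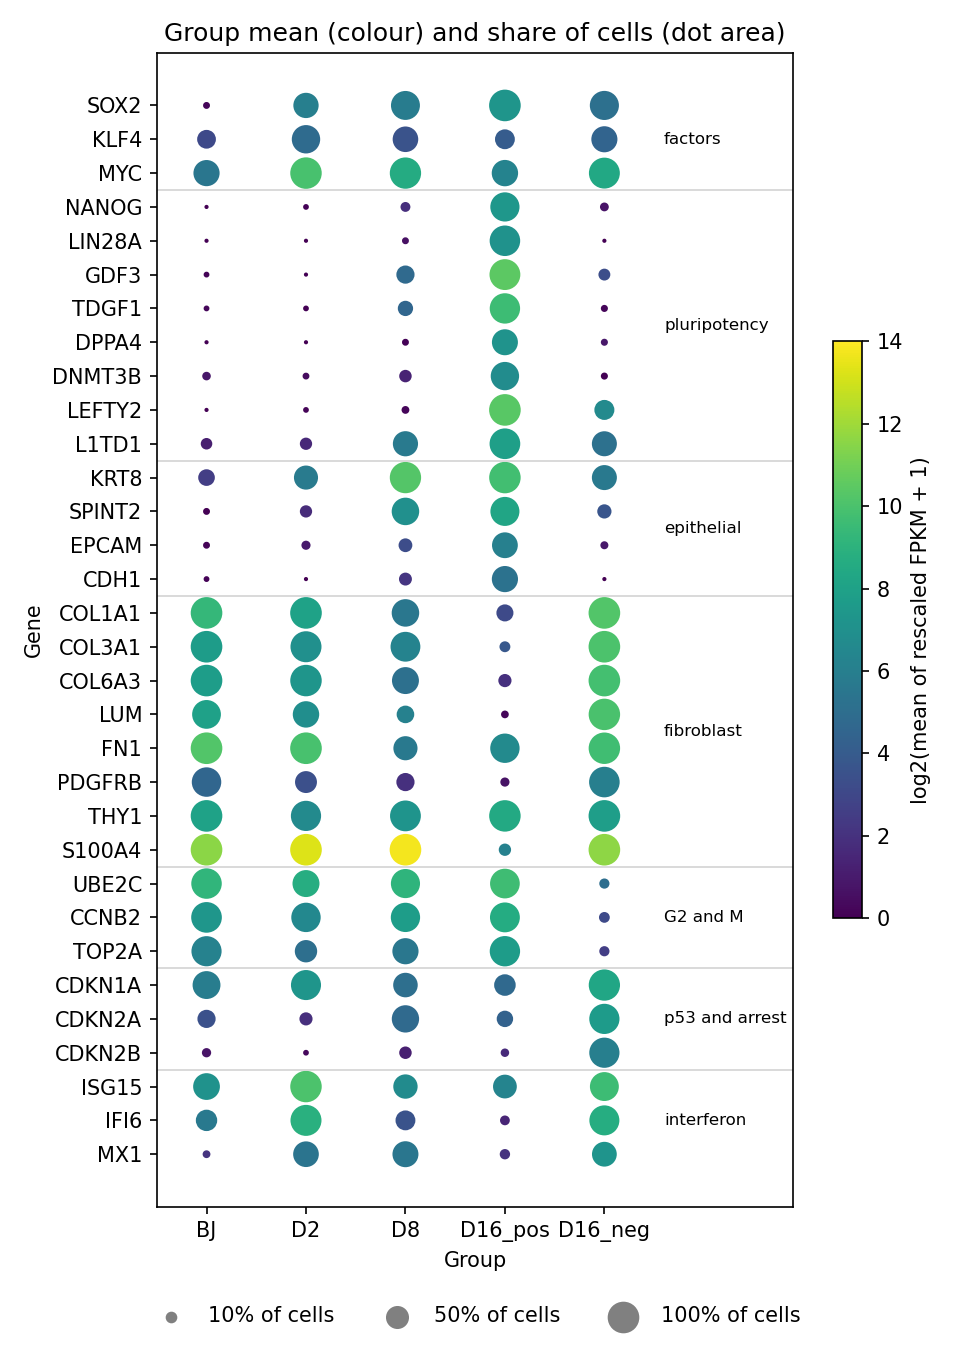
Mean level (colour, log2 of mean rescaled FPKM + 1) and share of kept cells at 1 or more (dot area) of genes from the fixed lists in the 5 groups. GDF3, TDGF1 and NANOG have their highest means in D16_pos (1401, 770.2 and 172), and COL1A1, COL3A1 and LUM in D16_neg (1162, 1029 and 999).

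The first comparison asked how cells at day 2 of factor expression differed from BJ cells. At day 2, MYC stood 21.7-fold above BJ cells and was detected in 98.96% of cells. Contractile and actin cytoskeleton genes were lower, with 9 of 14 measured members at least 2-fold lower, none higher and a list median of -1.43 (percentile 0). ACTA2, the smooth muscle actin of contractile fibroblasts, averaged 464 in BJ and 98.9 at day 2, TGFB1I1, a focal adhesion protein, averaged 125 and 28.5, and the tropomyosin TPM1 averaged 2708 and 1013. Of 34 fibroblast genes, 11 were at least 2-fold lower and 1 was higher, with a median of -0.48 (percentile 0.04). COL1A1 averaged 635 in BJ and 264 at day 2, and GREM1, a secreted BMP antagonist, 248 and 101, while FN1 averaged 1182 and 971. S100A4, the member that was higher, averaged 2975 and 9844.

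Immediate-early and adhesion-linked regulators were lower at day 2 as well. AP-1 factors had 6 of 11 members at least 2-fold lower and none higher (median -1.27), among them FOS (566 in BJ and 199 at day 2) and JUN (20.4 and 4.55), whereas FOSL1 averaged 54.3 and 43.3. In the TEAD and YAP list 6 of 12 were lower and none higher (median -1.01), including the YAP target CYR61, at 345 and 129.6; TEAD4 averaged 6.83 and 3.49, but its difference of mean log2 values had the opposite sign (0.40). Mesenchymal factors and markers had 4 of 12 members lower (median -0.94), with SNAI2 at 60.002 and 18.9. G2 and M phase genes had 8 of 28 lower (median -0.72), including TOP2A (68.9 and 32.9), and S phase genes 1 of 28 (median -0.33). The 10 lowest genes by difference of mean log2 level were ADM, ID3, ACTA2, TGFB1I1, GREM1, CTHRC1, TMSB15A, FHL1, HOXA10 and OXTR. ADM, which encodes the vasodilator adrenomedullin, averaged 386 in BJ and 46.9 at day 2, the BMP target ID3 464 and 108, the homeobox gene HOXA10 65.1 and 9.5, and the oxytocin receptor gene OXTR 139.5 and 39.6.

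Interferon response genes stood higher at day 2 than in BJ, with 18 of 22 measured members at least 2-fold higher, none lower and a median of 1.97 (percentile 100). IFI6 averaged 49.7 in BJ and 470.1 at day 2, ISG15, a ubiquitin-like modifier induced by interferon, 138 and 1034, and MX1, an antiviral GTPase, 3.37 and 41.03. RPL21 and several genes with near-identical copies stood apart in the same tables, day 2 and the negative fraction, with RPL21 at 4.45 in BJ and 1225 at day 2. Epithelial genes had 8 of 12 measured members higher and 2 lower (median 1.76, percentile 100), among them JUP, a junction protein (0.452 and 28.1), and the keratin KRT18 (289 and 1214), while CDH1 and EPCAM averaged 0.024 and 0.941. Of 19 p53 and senescence genes, 7 were higher and 2 lower (median 0.50). The cell cycle inhibitor CDKN1A averaged 58.5 in BJ and 156 at day 2, and CDKN2A 10.2 and 2.63. Further genes among the 10 highest were CKB, a creatine kinase (25.1 and 259.8), the imprinted noncoding RNA H19 (0.308 and 156), PTGES, a prostaglandin E synthase (3.34 and 129), IFI30 (14.2 and 131) and CD55, which restrains complement (11.2 and 115). HNRNPA1P10, a pseudogene copy of HNRNPA1 (2.58 and 119), and the globin gene HBA2, listed at 0 in BJ and at 374 at day 2, completed them. Pluripotency genes were mostly unmeasured, with 5 members at a mean of 1 or more in either group and a median of 0.37 (percentile 82.1). The fibroblast median depended on the scale: it was -0.09 from FPKM as deposited, where the median of all genes was 0.17, and -0.79 from the mean of log2 values, where that median was 0.02. As differences of mean log2 values, the medians were -0.26 for AP-1, 0.80 for interferon and 0.48 for epithelial genes.

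Between day 2 and day 8 the fibroblast programme was lower and an epithelial one higher. Of 34 fibroblast genes, 19 were at least 2-fold lower at day 8 and none higher, with a median of -1.06 (percentile 0); taken from FPKM as deposited, the median was -1.73. FN1, the adhesive matrix protein fibronectin, averaged 971 at day 2 and 50.1 at day 8, detected in 100% and 55.4% of cells, COL1A1 averaged 264 and 45.6, and BGN, a matrix proteoglycan, 66.7 and 4.19. Epithelial genes had 15 of 21 members higher and 1 lower (median 1.75, percentile 100). KRT8, a keratin of simple epithelia, averaged 53.6 and 1230.1, SPINT2, a membrane protease inhibitor, 2.26 and 124, and KRT18 1214 and 3203, whereas CDH1, the epithelial cadherin, reached 3.5 and was detected in 13.04% of day-8 cells (interval 6.93 to 21.7).

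Other gene groups differed alongside. Fibroblast surface markers had 5 of 10 lower and 1 higher (median -0.96), with CD44 at 268 and 111 and CD248 at 188 and 17.7; PROCR averaged 94.9 and 94.6. Contractile genes had 5 of 13 lower and 1 higher (median -0.76), including TAGLN (1528 and 296), and AP-1 factors 5 of 11 lower and 1 higher (median -0.96), including FOS (199 and 50.8). Interferon genes were lower, 19 of 22 by at least 2-fold and none higher (median -2.45), with IFI6 at 470.1 and 10.96 and ISG15 at 1034 and 104; RPL21 averaged 1225 and 5.9 in the same tables. Cholesterol synthesis genes were higher in 12 of 19 members and lower in none (median 1.12, percentile 100), including FDFT1, which makes squalene (180.4 and 581), and IDI1 (35.8 and 115), whose directions turned from FPKM as deposited. Some pluripotency genes stood above day 2, with 7 of 10 measured members higher and none lower (median 1.58). L1TD1, an RNA-binding protein of pluripotent cells, was detected in 60.9% of day-8 cells, GDF3, a TGF-beta family ligand, in 29.3% and TDGF1, a co-receptor of Nodal, in 19.6%. S phase genes had 4 of 28 members higher and 1 lower (median 0.58), and the G2 and M phase median of 0.46 turned to -0.05 when cells were scaled on housekeeping genes. As differences of mean log2 values, the medians were 0.53 for epithelial, 0.47 for pluripotency and -1.08 for interferon genes.

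The 10 highest genes by difference of mean log2 level were ANXA3, AKR1C1, KRT8, PLA2G16, C19orf33, OLFML3, SPP1, CD83, CD24 and UPP1. SPP1, the secreted glycoprotein osteopontin, averaged 12.9 at day 2 and 1398 at day 8, the annexin gene ANXA3 17.3 and 763, AKR1C1, an aldo-keto reductase, 27.2 and 526, OLFML3 59.05 and 1705, CD24, a surface glycoprotein, 7.84 and 311, and UPP1, a uridine phosphorylase, 30.4 and 331. The lowest genes included FN1, IFI6, ISG15, HNRNPA1P10 (119 and 0.138), GOLGA2P6 (392 and 0.068), ZNF628 (169.9 and 0.435), BCS1L (2181 and 59.7) and ZBTB33 (154 and 1.8). GOLGA2P6 and ZNF628 belong to 15 genes detected in at least 80% of BJ, day-2 and positive-fraction cells and in at most 25% of day-8 and negative-fraction cells, and BCS1L and ZBTB33 had their higher means in the same 3 groups.

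The third comparison set the fractions of day 16 against each other. Pluripotency genes were higher in the positive fraction in 27 of 27 measured members, with a median of 3.83 (percentile 100), and 30 of 34 fibroblast genes were at least 2-fold lower there, none higher, with a median of -3.44 (percentile 0). GDF3 averaged 1401 in the positive and 8.99 in the negative fraction, TDGF1 770.2 and 0.127, NODAL 509 and 0.142, and NANOG 172 and 0.639, detected in 84.2% and 4.71% of cells. The collagen genes COL1A1 and COL3A1 averaged 7.75 and 13.2 in the positive fraction and 1162 and 1029 in the negative fraction, and LUM, a matrix proteoglycan, 0.154 and 999. PODXL, which carries the sorted epitope, averaged 130.03 and 54.9.

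Cell cycle genes separated the fractions as widely. All 28 G2 and M phase genes were at least 2-fold higher in the positive fraction (median 4.05), and 27 of 28 S phase genes (median 3.19). UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, averaged 817 and 30.8, CDK1 428 and 17.3, and HELLS, a chromatin remodeller of S phase, 108 and 0.777. Among p53 targets and senescence genes 11 of 20 were lower in the positive fraction and 1 higher (median -1.04). The inhibitors CDKN1A, CDKN2A and CDKN2B averaged 25.9, 19.5 and 2.2 in the positive and 313, 199.6 and 61.3 in the negative fraction. Inflammatory and SASP genes had 10 of 13 members lower in the positive fraction and none higher (median -2.37), with the chemokine CXCL1 at 11.4 and 229. Interferon genes were lower there in 22 of 23 members and higher in 1, HERC5 (median -3.42), with IFI6 at 1.69 and 411 and IFI27 at 1.79 and 322; RPL21 averaged 2.49 and 992 in the same tables.

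Epithelial genes were higher in the positive fraction in 16 of 22 members and lower in 1, CLDN4 (median 2.89), with CDH1 at 37.6 and listed at 0 in the negative fraction, EPCAM at 64.3 and 0.843, and KRT8 at 871 and 49.7. Mesenchymal factors and markers had 9 of 10 members lower and 1 higher, CDH2 (median -2.12), with ZEB1, a repressor of epithelial genes, at 3.51 and 55.4. Of 10 fibroblast surface markers 8 were lower (median -3.59), with CD44 at 9.19 and 158, ANPEP at 0.231 and 15.96 and PROCR at 16.6 and 127, but THY1 averaged 351 and 222. Contractile genes had 8 of 14 lower (median -1.14) and AP-1 factors 8 of 11 (median -1.27). DNA methylation and chromatin genes had 11 of 25 members higher and 1 lower (median 0.87), led by the methyltransferase DNMT3B at 108 and 0.031 and by JARID2, a Polycomb cofactor, at 87.3 and 9.52. Further genes among the 10 highest were ESRG, a noncoding RNA of pluripotent cells (508 and 0.881), SPP1 (4736 and 154), the metallothioneins MT1G (1647 and 3.96) and MT1X (4394 and 94.1), and GOLGA2P6 (964 and 0.12) and ZNF628 (473 and 0.854) of the 15 genes above. The lowest were S100A4 (68.2 and 3135), S100A6 (185 and 10504), COL3A1, LUM, COL1A1, COL6A3 (2.81 and 888), COL1A2 (76.8 and 3401), MFAP4, an elastic fibre component (84.1 and 2584), S100A16 (75.999 and 1261) and the actin-severing GSN (98.1 and 1685). Scaling on housekeeping genes put the median of all genes at 0.86 and those of the pluripotency and fibroblast lists at 5.23 and -2.66; with only cells of at least 4000 genes, the pluripotency median was 4.47. As differences of mean log2 values, the medians were 1.19 for epithelial, -1.01 for inflammatory, -1.53 for interferon and -2.22 for contractile genes.

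**Figure D3:**
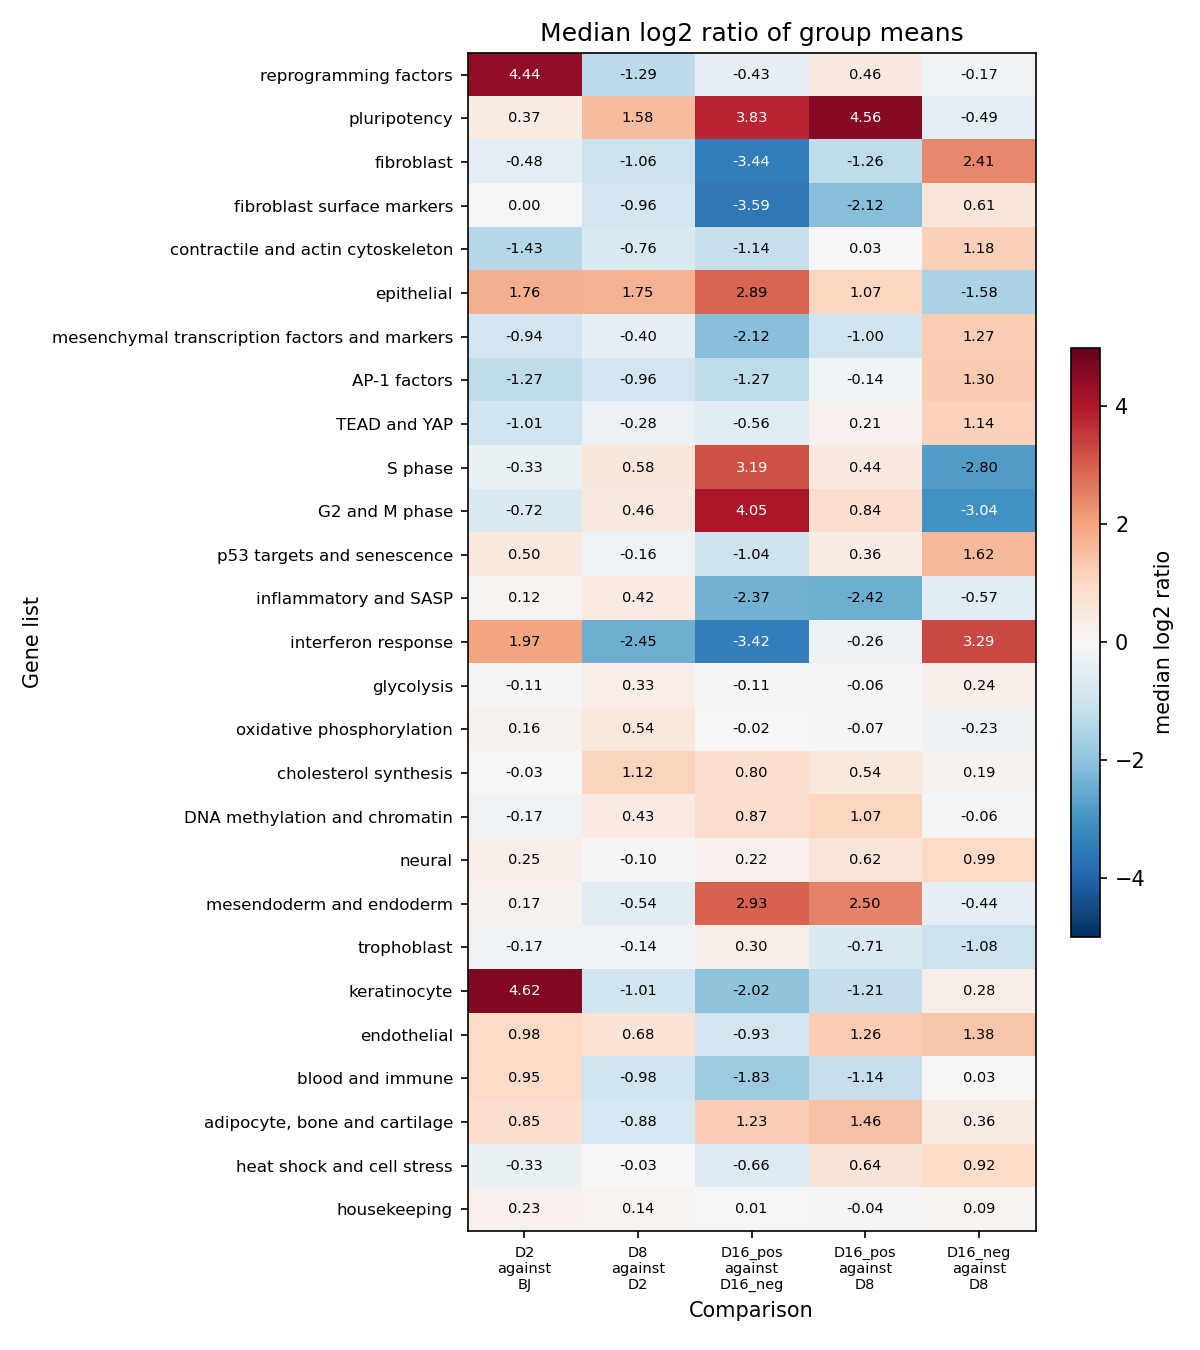
Median log2 ratio of group means over the measured members of each of the 27 gene lists in the 5 comparisons, with red for higher and blue for lower in the group named first. The pluripotency list has medians of 3.83 and 4.56 in the comparisons that start with D16_pos; the G2 and M phase list is at 0.46 in D8 against D2, where its sign turns under housekeeping scaling.

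The positive fraction was also set against day 8, to describe the state that goes with the TRA-1-60 epitope. Again 27 of 27 measured pluripotency genes were higher, with a median of 4.56 (percentile 100) against a median of 0.49 over all genes. The Nodal antagonists LEFTY1 and LEFTY2 averaged 0.115 and 0.149 at day 8 and 493 and 1328 in the positive fraction, NODAL 0.112 and 509, GDF3 26.5 and 1401, TDGF1 22.96 and 770.2, ESRG 29.05 and 508, and DPPA4 0.051 and 146. Fibroblast genes were lower in 21 of 34 members and higher in 2, THY1 and PDGFRA (median -1.26, percentile 0). S100A4 averaged 14077 at day 8 and 68.2 in the positive fraction, where 11.6% of cells held it (interval 5.92 to 19.8).

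Epithelial genes had 12 of 23 members higher and 4 lower than at day 8 (median 1.07). CDH1 averaged 3.5 and 37.6, EPCAM 8.41 and 64.3, and the splicing regulator ESRP1 0.586 and 101, while the keratins KRT18 and KRT19 were lower (3203 and 166 at day 8, 1568 and 61.1 in the positive fraction). Inflammatory and SASP genes had 12 of 14 members lower and none higher (median -2.42), with IL1B at 217 at day 8 and listed at 0 in the positive fraction. Fibroblast surface markers were lower in 7 of 9 (median -2.12). DNA methylation and chromatin genes were higher in 13 of 26 and lower in 1, DNMT3L (median 1.07), with TET1, which oxidises methylated cytosine, at 1.66 and 16.2. G2 and M phase genes had 9 of 28 members higher and none lower (median 0.84), including TOP2A (46.3 and 206). S phase genes had 3 of 28 higher, with a median of 0.44 (percentile 60.8) that turned to -0.25 as a difference of mean log2 values. Besides S100A4, the lowest genes were S100A6 (8427 and 185), the noncoding RNAs CYTOR (1190.4 and 109) and H19 (715 and 128), ANXA1 (1691 and 105), S100A16, TSPO of the outer mitochondrial membrane (530.4 and 11.02), ADIRF, IGFBP6 (463 and 28.8) and the galectin LGALS1 (5534 and 337). Among the 10 highest, GOLGA2P6, ZNF628 and ZNF667 (0.531 and 164) belong to the 15 genes above, and ZBTB33 (1.8 and 623) follows the same groups. The shift of all genes depended on the scale, from 1.13 under housekeeping scaling to -0.09 as a difference of mean log2 values, where the pluripotency medians were 5.36 and 2.95. On the latter measure the medians were -0.70 for inflammatory, 0.34 for DNA methylation and chromatin, and 0.13 for G2 and M phase genes.

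The negative fraction was set against day 8 in the last comparison, to describe cells of day 16 without the epitope. Fibroblast genes were higher than at day 8 in 26 of 34 members and lower in 1, S100A4, with a median of 2.41 (percentile 100) against 0.49 over all genes. COL1A1 averaged 45.6 at day 8 and 1162 in the negative fraction, FN1 50.1 and 847, LUM 66.3 and 999, and COL6A3 33.7 and 888. Cell cycle genes were lower, all 28 of the G2 and M phase list by at least 2-fold (median -3.04) and 25 of 28 of the S phase list (median -2.80). CCNB2, a mitotic cyclin, was detected in 84.8% of day-8 cells and 8.24% of negative cells (interval 3.38 to 16.2), and UBE2C in 83.7% and 7.06%.

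Of 20 p53 targets and senescence genes, 16 were higher in the negative fraction and 1 lower, LMNB1 (median 1.62, percentile 100). CDKN2B averaged 1.31 at day 8 and 61.3 in the negative fraction, CDKN2A 26.6 and 199.6, CDKN1A 32.1 and 313, and the stress cytokine GDF15 33.1 and 221. Inflammatory and SASP genes had 4 of 15 members higher and 6 lower, with a median of -0.57 that turned to 0.09 as a difference of mean log2 values and to 1.40 with trimmed means. All 23 measured interferon genes were higher (median 3.29); RPL21 averaged 5.9 and 992 in the same tables. Epithelial genes were lower in 14 of 20 and higher in 1, JUP (median -1.58), with KRT8 at 1230.1 and 49.7. Contractile genes were higher in 10 of 14 (median 1.18), with ACTA2 at 18.03 and 251, AP-1 factors in 6 of 11 (median 1.30), with FOS at 50.8 and 476, TEAD and YAP genes in 7 of 12 (median 1.14), and mesenchymal factors and markers in 7 of 11 (median 1.27). The pluripotency median of -0.49 over 13 measured genes turned to 0.18 with no cell left out. As differences of mean log2 values, the medians were 1.63 for interferon and -0.46 for epithelial genes. The highest genes besides these were MFAP4 (72.1 and 2584), the matrix proteoglycan ASPN (2.4 and 359.9), the stress regulator NUPR1 (30.1 and 662), RAMP1, which pairs with the calcitonin receptor-like receptor (3.05 and 511), RCN3 (10.99 and 223) and the heparan sulfatase SULF1 (11.6 and 268). The lowest were TK1, a thymidine kinase of S phase (466 and 45.2), PCLAF (280.4 and 6.64), UBE2C, MAD2L1 of the spindle checkpoint (278 and 20.2), CCNB2, KRT8, SNHG19 (220.1 and 32.5), securin PTTG1 (798 and 82.9), and the near-identical copies UQCRHL (619 and 21.04) and ATP5EP2 (116 and 12.8), whose values can hold reads of UQCRH and ATP5E.

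Shares of cells with each programme were counted cell by cell. A pluripotency programme, at least 3 of 29 list genes at 1 or more with PODXL not counted, was found in 3 of 92 BJ cells (3.26%, interval 0.678 to 9.24), 6 of 96 at day 2 (6.25%, 2.33 to 13.1), 39 of 92 at day 8 (42.4%, 32.1 to 53.1), 95 of 95 in the positive fraction (100%, 96.2 to 100) and 31 of 85 in the negative fraction (36.5%, 26.3 to 47.6). The median cell held 15 of these genes in the positive fraction and 2 both at day 8 and in the negative fraction. In the negative fraction the genes seen most often were TERF1, a telomere-binding protein also detected in 40.2% of BJ cells (69.4%), L1TD1 (60%) and LEFTY2 (36.5%), whereas NANOG was in 4.71%. A fibroblast programme, at least 17 of 34 list genes, was found in all 92 BJ cells and all 96 day-2 cells, in 75 of 92 at day 8 (81.5%, 72.1 to 88.9), 17 of 95 in the positive fraction (17.9%, 10.8 to 27.1) and all 85 kept cells of the negative fraction. Both programmes were present in 27 of 92 day-8 cells (29.3%, 20.3 to 39.8), and neither in 5 of 92 (5.43%, 1.79 to 12.2). The shares at day 8 and in the negative fraction rested on the level that counts as detected: at 10 or more, 14.1% of day-8 cells and 15.3% of negative cells had the pluripotency programme, and 5.26% of positive cells the fibroblast programme. The positive fraction also held the largest part of low-complexity cells, in which fewer list genes can be seen; among its cells of at least 4000 genes, 26.98% had the fibroblast programme.

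**Figure D4:**
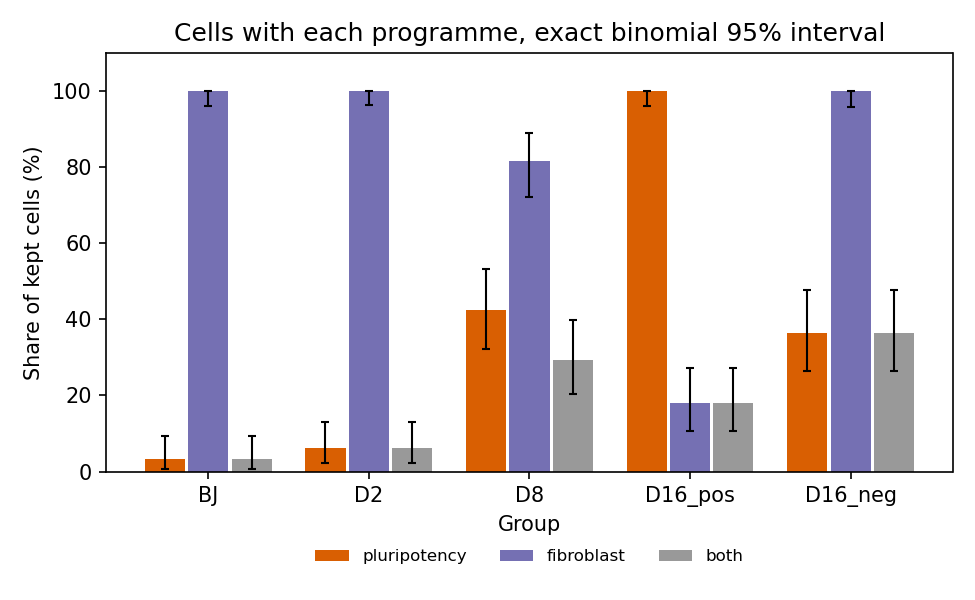
Share of kept cells in each group with at least 3 pluripotency genes, with at least 17 fibroblast genes, and with both (bars), with exact binomial 95% intervals (lines) that cover counting error only. The pluripotency programme is in 42.4% of D8, 100% of D16_pos and 36.5% of D16_neg cells.

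**Figure D5:**
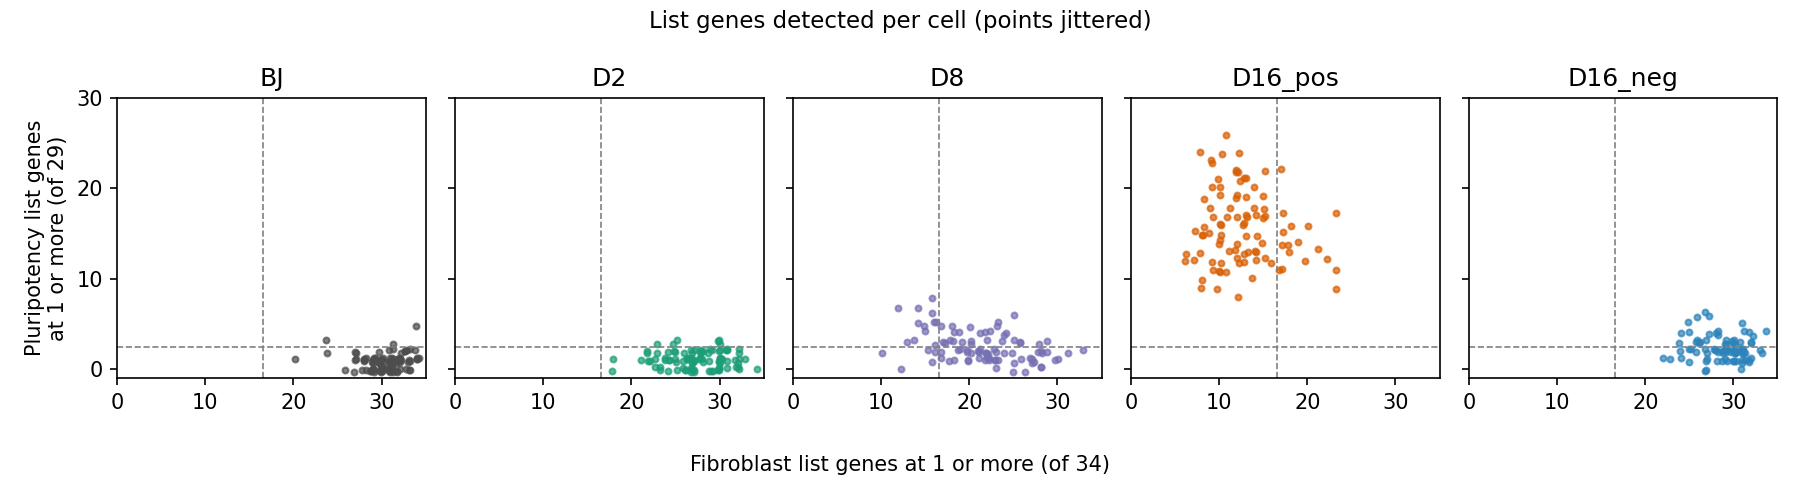
Number of pluripotency genes (vertical axis) and fibroblast genes (horizontal axis) at 1 or more in each kept cell (points, jittered), with the minimum for each programme as dashed lines. The median D16_pos cell has 15 pluripotency and 12 fibroblast genes, and the median D16_neg cell 2 and 29.

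Profiles of the groups were compared over 15120 genes. Spearman rho of group means, across genes that are not independent replicates, was 0.883 between BJ and day 2, 0.865 between day 2 and day 8, 0.855 between day 8 and the negative fraction and 0.780 between day 8 and the positive fraction. The fractions of day 16 had a rho of 0.726, and BJ had 0.792 with the negative and 0.728 with the positive fraction. Pairs of cells within the positive fraction, which held the most low-complexity cells, had a median rho of 0.383, against 0.524 to 0.565 within the other groups.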

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

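No test was run on the differences given here, and none was chosen after the results were seen. Lists were flagged where the medians of the 2 fractions against day 8 had opposite signs and were both 1 or more in size. The fibroblast and the epithelial list met this rule. Other lists had opposite signs with a smaller median in at least 1 fraction. Among them were mesenchymal factors and markers (-0.999 in the positive and 1.27 in the negative fraction), G2 and M phase (0.84 and -3.04) and fibroblast surface markers (-2.12 and 0.61). The fibroblast list median against day 8 was -1.26 in the positive and 2.41 in the negative fraction, with 21 of 34 members at least 2-fold lower in the former and 26 of 34 higher in the latter. The epithelial list median was 1.07 in the positive and -1.58 in the negative fraction. The difference between the fractions was not tested, as each is 1 culture, and day 8 serves as the common reference of both. In each of these comparisons the median of all genes was itself 0.49. THY1 and PDGFRA were at least 2-fold higher in the positive fraction than at day 8, while the list median lay below 0, with THY1 at 149.9 and 351. S100A4 was lower than at day 8 in both fractions (14077 at day 8, 68.2 in the positive and 3135 in the negative fraction).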

How the results depend on the processing

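Leaving small RNA genes out of the rescaling was chosen only after the data were seen, as were all alternatives for the fibroblast list medians of the positive against the negative fraction and against day 8 and for the day-8 pluripotency share; those results themselves were planned. The 77 alternative medians covered the fibroblast list in all 5 comparisons and the pluripotency list in both comparisons of the positive fraction. Of these, 65 moved by less than 1.5-fold or not at all, 12 moved by more and none changed sign. All 34 fibroblast genes were measured in every comparison, so taking all list members could not move a fibroblast median. A changed pseudocount keeps the direction of each gene, which made a turn of a median unlikely. The pluripotency median of the negative fraction against day 8 was not among the 77 and did change sign with no cell left out. Of 35 alternative shares, 26 stayed within the interval and 9 left it. The direction of the 10 highest and 10 lowest genes of each comparison was kept in 1000 of 1000 combinations of gene and setting. These genes had been chosen by the difference of mean log2 values, and a changed pseudocount cannot turn a direction. Neither of those settings could therefore fail, and the choice of large differences made a turn unlikely in the others. Among genes named from the lists or fixed, 60 of 543 combinations of gene and comparison turned in at least 1 setting, 11 of them among the 371 with a log2 ratio of 1 or more in size. Over all 27 lists and 5 comparisons, 84 of 135 medians moved by more than 1.5-fold in at least 1 setting and 46 changed sign; the difference of mean log2 values moved 48, trimmed means 40 and housekeeping scaling 38. No paired analysis was possible because the cell numbers that the groups share name cells and not cultures. No difference between groups was tested.

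In the positive against the negative fraction, the pluripotency median of 3.83 became 5.23 under housekeeping scaling, 6.40 with a pseudocount of 0.1, 4.85 with trimmed means and 4.47 with cells of at least 4000 genes; the fibroblast median of -3.44 became -2.66 under housekeeping scaling, -4.48 as a difference of mean log2 and -4.61 with trimmed means. In the positive fraction against day 8, the pluripotency median of 4.56 became 5.36 under housekeeping scaling, 5.97 with a pseudocount of 0.1, 2.95 as a difference of mean log2 and 3.80 over all list members. In day 8 against day 2, the fibroblast median of -1.06 became -1.73 from FPKM as deposited. A smaller pseudocount widens ratios of genes near 0 by construction, and unmeasured members draw a median towards 0; for the other settings the cause was not tested. The fibroblast median of day 2 against BJ ranged from -0.79 to -0.09, that of the positive fraction against day 8 from -1.62 to -0.79 and that of the negative fraction against day 8 from 2.17 to 2.93.

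The pluripotency share of day-8 cells was 42.4%, 75% with any value above 0, 14.1% at 10 or more and 11.96% among the 3000 highest genes; in the negative fraction it was 36.5%, and 15.3% and 8.24% in the last pair of settings. The fibroblast share of positive cells was 17.9%, 29.5% with any value above 0, 5.26% at 10 or more, 2.11% among the 3000 highest genes and 26.98% with only the 63 cells of at least 4000 genes; stricter detection lowers a share by construction. The fibroblast share of the negative fraction was 88.5% with no cell left out, which returned the 11 cells of few genes, against 100%. The pluripotency median of the negative fraction against day 8 was -0.49, 0.18 with no cell left out and 0.00 with trimmed means.

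The median of all genes shifted with the scaling. FPKM as deposited put it at 0.17 in day 2 against BJ, -0.12 in day 8 against day 2, 0.18 in positive against negative, 0.33 in positive against day 8 and 0.23 in negative against day 8; housekeeping scaling put it at -0.09 in day 8 against day 2, 0.86 in positive against negative and 1.13 in positive against day 8. Without small RNA genes in the rescaling it was 0.18 in positive against negative and 0.60 in positive against day 8, and without mitochondrial RNA genes 0.18 in positive against negative. The depth of the cells is unknown, which limits every share of cells near 0.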

Other observations

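The correlation of the 15-gene set with detected genes over positive cells, and its comparisons with random sets, were weighed as a test only after the correlation was seen, and both tests on POU5F1 were chosen only after its values were seen; the others were set beforehand. Keratin genes of stratified epithelium stood above BJ at day 2: of 8 measured keratinocyte genes, 7 were at least 2-fold higher and none lower, with a median of 4.62 (percentile 100), or 2.13 as a difference of mean log2 values. KRT6A, a keratin of activated keratinocytes, was listed at 0 in BJ, at 253 at day 2 in 61.5% of cells, and at 59.3 at day 8, and KRT14 averaged 81.6 and 9.96, while the other markers KRT5, TP63 and DSG3 averaged at most 0.043, 0.0136 and 0.0113 in BJ and day-2 cells. The list was lower at day 8 than at day 2 (median -1.01) but still stood above BJ. Against BJ, 8 of 10 measured members were at least 2-fold higher at day 8 and 1 was lower (median 2.14). The keratinocyte list was also lower in the positive against the negative fraction (median -2.02), where KRT17 averaged 1.07 and 129. Globin genes were listed in day-2 cells too, HBA2 at 374 in 63.5% of cells and HBA1 at 10.7, with 3 of 8 measured blood genes higher and 1 lower (median 0.95), while GATA1 and TAL1, regulators of red cells, were at 0 and 0.018 at day 2.

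Lineage genes differed between the fractions of day 16. Of 18 mesendoderm and endoderm genes, 6 were measured. All 6 were higher in the positive fraction (median 2.93, and 0.59 as a difference of mean log2 values). They included MIXL1 (13.7 and 0.206, in 25.3% and 1.18% of cells) and WNT3 (14.1 and 0.765). MIXL1 and WNT3 reached a mean of 1 in the positive fraction only, so as measured genes they could only be higher there. Neural genes had 4 of 9 higher and 3 lower, with ZIC2 at 22.1 and STMN2 at 2.22 against 200.2. The neural list median of 0.22 (percentile 65.1) turned to -1.46 at its lowest setting. Adipocyte, bone and cartilage genes had 5 of 9 higher and 1 lower, COMP (0.508 and 411). In the negative fraction against day 8 the endothelial list had 4 of 6 members higher, with a median of 1.38 that was 0.26 as a difference of mean log2 values. TEK led them (14.2 and 37.7), while PECAM1 and CDH5 averaged 0.498 and 0.0557 in the negative fraction and KDR was listed at 0. The trophoblast list had 1 higher and 5 lower of 9 (median -1.08, and -0.02 with trimmed means). The stress list had 6 of 14 members higher and 2 lower (median 0.92), including DDIT3 of the unfolded protein response (28.3 and 203). Of 24 oxidative phosphorylation genes, 3 were higher at day 8 than at day 2 and none lower (median 0.54, and 1.20 as a difference of mean log2 values); glycolysis genes had 3 higher and 1 lower of 20, with a median of 0.33 that turned to -0.03 from FPKM as deposited. The housekeeping list had 2 of 16 members higher and 2 lower in the positive against the negative fraction, and the median of 0.01 ranged from -0.48 to 0.55 over settings. The reprogramming factor list had all 3 measured members higher at day 2 than in BJ (median 4.44).

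POU5F1 was listed at or near 0 in all 5 groups. That the gene was not expressed stays open: the median over 10 widely expressed neighbours of their highest group mean was 0.0245, and a stretch that is not measured cannot speak against it, so the bound set for this test was dropped after the result was seen. Near-identical copies outside the stretch were highest in the positive fraction, POU5F1P3 at 20.2, POU5F1B at 12.3 and POU5F1P4 at 7.31, and at most 0.43, 0.233 and 0.296 in the other groups; such values go against no expression in the positive fraction only if they hold reads of POU5F1, which the tables do not show. Loss of reads from the whole stretch before the values were made is a candidate explanation, since 0.667% of its protein-coding genes (1 of 150) had a mean of 10 or more, against 39.3% of as many genes on either side.

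The 15 genes detected in BJ, day-2 and positive cells, and not at day 8 or in the negative fraction, included GOLGA2P6, ENKUR and FOXB2. The low-value steps of whole reads split the groups alike. Pairs of cells with steps were more frequent at day 8 and in the negative fraction than in the other groups. Whether both patterns come from how the tables were made was not tested. Day 8 against day 2, and the positive fraction against the negative fraction and against day 8, are comparisons across this split. Expression by the cells was weighed by the course of the 15 genes within the positive fraction. Their summed level had a rho of -0.81 with the number of detected genes over 95 cells. The 10000 random sets matched on mean and share of cells had a median rho of 0.13 and a lowest of -0.587. Among the 63 cells of at least 4000 genes the rho was -0.65, and the lowest of these sets had -0.567. Such a fall had been set to count against expression by the cells. The random sets drew each gene separately, however, and genes that vary together can reach a larger rho. Genes expressed mostly in cells of few detected genes would fall alike, so expression by the cells stays open. Signal brought in by the library work may account for it and stays open: in the 4 BJ cells left out for few genes, 57.1% of gene and cell pairs were at 1 or more, against 39.3% for other genes with the same share of kept cells, a gap of 17.8 points where 25 had been set beforehand.

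Interferon genes were higher at day 2 and in the negative fraction, the tables in which RPL21 and its copies also stand apart (RPL21P28 averaged 4059.9 and 3816 there, and at most 10.5 elsewhere). Reads shared with near-identical copies may explain RPL21. Copies of interferon genes were sought by symbol only, as the gene's own symbol followed by P, L or P with a number. By that rule 4.17% of the interferon genes (1 of 24, IFI44) have a listed copy, and the match, IFI44L, is itself on the list. The low share goes against copies so named as the source for the list. Copies under other names were not sought, so shared reads with those stay open. Rescaling each cell to the same total removes a shift of all genes of a table alike. The rescaled medians of all genes could therefore not show such a shift. They were -0.02 in day 2 against BJ and 0.49 in the negative fraction against day 8. Interferon medians there were 1.97 and 3.29, each at percentile 100. From FPKM as deposited, the medians of all genes were 0.17 and 0.23 in these comparisons, and the interferon medians 2.23 and 2.96. These unrescaled values argue against a shift of all deposited values of a table alike as the source for the list. A shift of only some genes in how the values of a table were made stays open. Interferon genes varied together most in the day-2 and negative tables. Their median pairwise rho was 0.18 over day-2 cells (percentile 99.99 of random lists) and 0.288 in the negative fraction (100). It was 0.0887 in BJ (98.1), 0.0678 at day 8 (99.3) and 0.0462 in the positive fraction (34.1). The bound set beforehand would have excluded a shift, but was set aside after the result was seen. A factor common to all cells of a table leaves ranks within it unchanged, and BJ and day 8 pass the bound too. A culture or infection run of its own for each table cannot be told apart from the day or fraction, since 0 groups were split over runs by the labels. An interferon response of the cells, which the design allows by day and fraction, is among the open explanations and was not tested.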
